A study of Gorilla gorilla gorilla with 14 samples.

How the data were processed

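Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters there. The material was 4 cell types sorted by flow cytometry from gorilla cerebral organoids in week 8 of culture, grown from the induced pluripotent stem cell line GC1. Per the labels' protocols, the cells were treated as for fixed material, with an overnight crosslink reversal after transposition, and libraries were size selected before sequencing. The groups were apical radial glia (aRG, n = 3), basal radial glia (bRG, n = 2), basal intermediate progenitors (bIP, n = 5) and neurons (N, n = 4). The library numbers in the labels form 2 runs of consecutive numbers, called the first and second library series here, with 7 libraries each. The first series held aRG replicates 1 and 2, bIP replicates 1 to 3 and N replicates 1 and 2. The second held aRG replicate 3, both bRG libraries, bIP replicates 4 and 5 and N replicates 3 and 4. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

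The deposited count table holds whole-number read counts per region and library, not normalized, as the authors made it. Per the submitters' processing notes, bcl2fastq 2.20.0 and MACS2 were used and the builds hg38 and panTro6 were involved. Per the file headers, the count table also names each region in gorGor6, and all coordinates here are gorGor6 positions taken from those region names, counted from 1. The aligner, the read counter, the MACS2 version and any shift of reads to the transposase cut site are not given in the sources used here. The authors deposited 1 consensus peak set per cell type, not per library, so replicates of a peak set cannot be compared. The peak sets state no genome build. They were taken as gorGor6 positions because 63.4% of the table's regions off chromosomes 2A and 2B were touched by a peak, and 11.6% after a shift of 50 kb. Values from these sets rest on that assumption. Per the file headers these sets are in narrowPeak layout, with a deposited score, a deposited fold enrichment (ratio) at the summit, and a deposited −log10 p-value and −log10 q-value by the peak caller. The −log10 q was used only to pick the stricter part of each set, and the score, the fold and the −log10 p entered no comparison.

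The count table has 218080 regions. The 13823 without a gorilla position, whose counts were all 0, were left out, as were 8 repeats, which left 204249 regions of a median 858 bp. Totals over these regions ranged from 12834983 to 26660427 counts per library. The table lists a closest gene and a distance for each region, and 2847 regions have none. A promoter region is one listed at a distance of at most 1000 bp from its gene. This distance was taken as that to the transcription start, which the file does not state. There were 20663 such regions, of which 10591 belonged to protein-coding genes. Of 39300 gene names, 12952 matched a protein-coding symbol or synonym in the RefSeq gene table of another gorilla assembly (NHGRI_mGorGor1-v2.1_pri), which was used for nothing else. Exon or intron positions were not used here.

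Counts were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, regions kept by filterByExpr on the groups (200931 regions), and a quasi-likelihood model with 1 mean per group and a term for the library series was fitted to all 14 libraries, which share 1 estimate of the spread over 9 residual degrees of freedom. Negative binomial dispersions followed the trend with abundance, and quasi-likelihood dispersions were estimated per region. All 6 pairs of groups were compared, and p-values were adjusted by Benjamini and Hochberg over all regions of a comparison, with a threshold of 0.05. A log2 fold change comes from this model, is given with its standard error, and need not equal the ratio of group means, since the series term enters it. Levels are CPM, counts scaled to the library total with TMM factors, as mean ± SD over the libraries of a group. A library's floor of 3 counts lay between 0.113 and 0.234 CPM. Floors, and the Wilson intervals of shares of peak sets, cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Intervals of log2 differences come from the model and rest on the spread between libraries.

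Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, using for each gene the promoter region with the highest mean count and adjusting over 15 lists and 6 comparisons. The lists were shared radial glia, apical radial glia, basal radial glia, basal intermediate progenitors, excitatory cortical neurons, the GABAergic lineage, choroid plexus and cortical hem, mesenchyme, oligodendrocyte lineage and astrocytes, pluripotent cells, cell cycle, Notch pathway, cell shape and adhesion (morphoregulatory), axon growth and synapse, and housekeeping. With a correlation estimated from the data, no list passed in any comparison, and the smallest adjusted p was 0.898. The share of promoters among changed regions was tested with Fisher's exact test, two-sided. Peak sets were compared with bedtools 2.31.1, counting a region as shared when at least 50% of it was covered, with Wilson intervals at 95% from scipy 1.17.1. Python 3.11.15 and pandas 2.3.3 were used for tables.

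The groups, tests, lists, most alternatives and the rule for named genes were set before the data were examined. In the comparisons of bRG with aRG, bIP with bRG and N with bIP, the rule took per direction the 8 promoter regions of protein-coding genes with the smallest p among those past the threshold, changed at least 2-fold and with no overlap of libraries. It added up to 4 members of each list past the threshold, the 6 genes EOMES, HOPX, PAX6, BCL11B, NEUROD2 and SOX2 whatever their p, and per direction the 3 distal regions with the smallest p. Other genes are named only as members of a list. Genes named for a difference between library series were chosen after their values were seen.

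The test was checked on simulated counts for 20000 regions with 200 changed, 50 at each fold. For bRG against aRG it recovered 12% of 2-fold, 70% of 4-fold and 86% of 8-fold changes, with 1 false call. The shares were 16%, 66% and 96% for bIP against bRG, with 1 false call, and 48%, 94% and 98% for N against bIP, with 2 false calls. Far fewer regions changed in the simulation than passed in these 2 real comparisons, so the shares do not carry over to them. The simulated libraries were independent, so the false calls do not cover libraries of 1 culture. Alternatives were the DESeq2 1.42.0 Wald test, 3 other scalings (DESeq2 size factors, total counts, loess offsets), other filters on low counts, models without the series term, within 1 series or with the groups compared alone, the replicate number as a block, each library left out in turn, other windows and correlations for the lists, and other overlaps for the peak sets. No genome sequence was used here, so the intended motif tests and correction for GC content were not run.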

Results

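Accessible chromatin was profiled in 4 sorted cell types of the developing cortex, taken from gorilla cerebral organoids, which are cultured tissues that form neural stem cells and their progeny from pluripotent cells. Apical radial glia (aRG) are the stem cells that line the ventricle. Basal radial glia (bRG) are stem cells that have left the ventricular surface, basal intermediate progenitors (bIP) are committed to making neurons, and neurons (N) are the product. The counts used covered 204249 regions. The mean total per library was 21843333 ± 4563030 counts in aRG (SD, n = 3), 19986901 ± 426310 in bRG (n = 2), 20506765 ± 6110409 in bIP (n = 5) and 19717729 ± 4800575 in N (n = 4). Single libraries ranged from 12834983 counts in bIP replicate 3 to 26660427 in aRG replicate 1. Promoter regions held 38.5% ± 0.580 of counts in aRG, 36.4% ± 0.454 in bRG, 35.6% ± 1.75 in bIP and 33.9% ± 3.67 in N.

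The cell types separated along the main axes of variation. The first principal component, with 57.8% of the variance, placed aRG and bRG at one end, bIP in the middle and N at the other. The second, with 20.5%, set bIP apart from the other cell types. The third, with 6.82%, separated the first library series from the second in every cell type that both series hold. All bRG libraries and aRG replicate 3 belong to the second series. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 1.07, for aRG replicates 1 and 2, and 1.11, for bIP replicates 1 and 2, up to 11 for a pair of N libraries. Each library was kept as 1 sample, which the test does not settle, since libraries of 1 culture can also differ by more than sampling noise. If the 2 closest pairs each came from 1 culture, n would be lower in aRG and bIP. With each of them summed, 77626 regions differed between bIP and aRG, 68895 between bIP and bRG and 104106 between N and bIP.

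**Figure D1:**
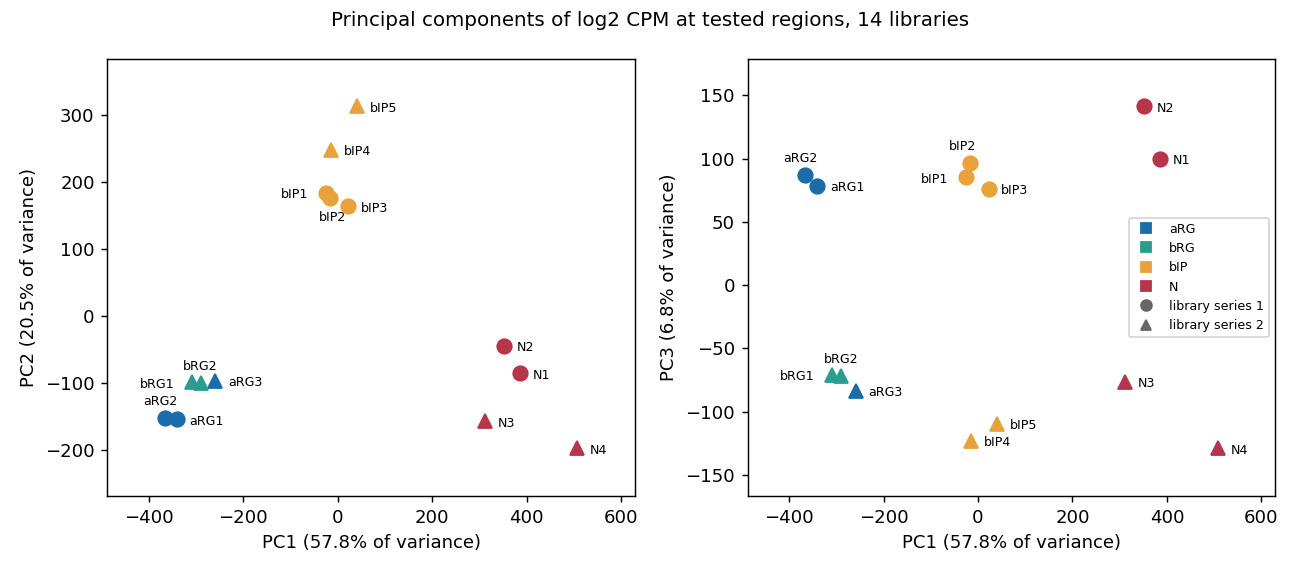
Principal components of log2 CPM at the tested regions, with 1 point per library, colours for cell types and symbols for library series; axes are component scores with the share of variance. The first component (57.8%) orders radial glia, bIP and N, and the third (6.8%) parts the library series.

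The comparison of bRG with aRG asks what distinguishes basal from apical radial glia. At the promoter of SOX2, a transcription factor of neural stem cells, accessibility was 59.3 ± 1.59 CPM in aRG (n = 3) and 49.0 ± 3.71 CPM in bRG (n = 2), a log2 difference of −0.51 ± 0.23 (SE, adjusted p = 0.987). HOPX, known as a marker of outer radial glia, stood at 25.2 ± 3.30 CPM in aRG and 20.9 ± 3.32 CPM in bRG (log2 −0.18 ± 0.27, adjusted p = 0.987). EOMES, the transcription factor that marks intermediate progenitors, stood at 31.5 ± 13 and 45.8 ± 0.732 CPM (log2 0.23 ± 0.22, adjusted p = 0.987). Its aRG libraries lay apart by series, at 22.4 and 25.7 CPM in the first and 46.4 CPM in the second. PAX6 (14.7 ± 1.02 and 14.4 ± 0.0541 CPM), BCL11B (19.7 ± 3.50 and 14.2 ± 0.987 CPM) and NEUROD2 (3.91 ± 2.56 and 5.32 ± 0.699 CPM) did not pass either, each with an adjusted p of 0.987.

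No region passed the threshold between bRG and aRG with edgeR's quasi-likelihood test, 0 of 200931, and the smallest adjusted p was 0.165. At an unadjusted p under 0.05 there were 8197 regions, where chance alone gives 10047, and DESeq2 called 7 regions, all lower in bRG. The 95% interval of the difference lay within 2-fold for 41.0% of regions and for 77.1% of promoter regions, and within 4-fold for 92.4% of regions, so at the other regions a 2-fold difference was not excluded at this depth and number of libraries. A fit to the aRG and bRG libraries alone, with the series term, gave 94 regions higher and 1031 lower in bRG. In that fit the difference is that of both bRG libraries from aRG replicate 3, and aRG replicates 1 and 2 enter through the series term and the spread. Of the 1031 regions 44.9% were higher in N than in bIP, against 25.7% of all regions of that fit. Without the series term it gave 0, with 21268 at an unadjusted p under 0.05, where chance alone gives 8923. Without aRG replicate 3 the model with all groups gave 4 higher and 7 lower, with 16185 at an unadjusted p under 0.05, where chance alone gives 10030. Within the second series, where aRG has 1 library and the other groups supply its spread, edgeR called 0 regions, with 4695 at an unadjusted p under 0.05, where chance alone gives 10056.

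No member of any of the 15 gene lists passed the test between bRG and aRG, over all regions or adjusted over the list alone. As a set, the promoters of shared radial glia genes, which include SOX2, HES1 and VIM, lay lower in bRG (median log2 −0.32 over 15 genes, camera adjusted p = 0.00994, and adjusted p = 0.898 with an estimated correlation). Without bRG replicate 2 the adjusted p was 0.0564. The call was lost in 9 of 20 alternatives. Among them were the fits without the series term, with loess offsets, with the 2 groups alone and within the second series, where aRG has 1 library. Housekeeping promoters had nearly the same median (−0.31 over 8 genes, adjusted p = 0.0816), and the median over all 19305 promoters was −0.20. Cell cycle (−0.28), Notch (−0.26) and excitatory neuron promoters (−0.25) also had medians below 0 without passing. The pluripotent cell list lay higher in bRG (median 0.71, adjusted p = 0.000895, and adjusted p = 0.898 with an estimated correlation), but only 2 of its 8 genes were measured, DPPA4 (1.54 ± 0.854 CPM in aRG and 2.97 ± 0.229 CPM in bRG) and LIN28A (0.653 ± 0.201 and 0.978 ± 0.190 CPM). Within the second series its adjusted p was 0.285. The basal radial glia list, with a median of −0.16 and an upward direction in the test, had an adjusted p of 0.741, and the apical list (median −0.16) had 0.937. The morphoregulatory list, of genes for cell shape, protrusion and adhesion, had a median of −0.24 over 21 genes and an adjusted p of 0.120. Median and test also differed in sign for the intermediate progenitor, GABAergic, choroid plexus, mesenchyme and oligodendrocyte lists, none of which passed. The lists other than shared radial glia and pluripotent cells had adjusted p from 0.0816 to 0.940, the latter for mesenchyme.

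Entry into the intermediate progenitor state was read from bIP against bRG. The promoter of NHLH1, a proneural transcription factor (chromosome 1, 130988036 to 130989211), rose from 3.39 ± 0.436 CPM in bRG (n = 2) to 29.8 ± 5.35 CPM in bIP (n = 5), a log2 change of 3.22 ± 0.31 (adjusted p = 6.4e-08). MYT1L, a transcription factor that represses non-neuronal genes (chromosome 2A, 18434719 to 18436294), rose from 5.90 ± 0.336 to 45.7 ± 8.64 CPM (log2 3.11 ± 0.26, adjusted p = 3.5e-08). EOMES rose from 45.8 ± 0.732 to 83.0 ± 19.8 CPM (log2 1.17 ± 0.21, adjusted p = 8.5e-05). NEUROD2, a transcription factor of excitatory neurons, rose from 5.32 ± 0.699 to 34 ± 6.87 CPM (log2 2.90 ± 0.33, adjusted p = 3.4e-07). NES, which encodes the filament protein of neural stem cells, fell from 17.0 ± 1.05 to 8.28 ± 1.10 CPM (log2 −0.91 ± 0.20, adjusted p = 0.00088).

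Of the other promoters with the smallest p, those of EIF4E1B (log2 3.28 ± 0.33), APOBEC4 (3.22 ± 0.35), NPPA (2.96 ± 0.32), TAC3 (2.83 ± 0.27), ZDHHC22 (2.81 ± 0.28) and NYAP2 (2.47 ± 0.24) rose in bIP. TAC3 encodes the precursor of neurokinin B and NPPA that of atrial natriuretic peptide. The promoters that fell were those of GCM1 (−3.02 ± 0.29), SLCO1C1 (−2.58 ± 0.30), BBOX1 (−2.54 ± 0.29), PDIA6 (−2.49 ± 0.30), KBTBD12 (−2.35 ± 0.24), A2ML1 (−2.33 ± 0.23), VCAM1 (−2.19 ± 0.26) and SLFN12 (−2.16 ± 0.23). SLCO1C1 encodes a thyroid hormone transporter and VCAM1 a cell adhesion molecule. The distal regions with the smallest p rose near LINC02264 (log2 3.51 ± 0.26, at 73752 bp), UMODL1-AS1 (3.74 ± 0.29, at 11500 bp) and HSPE1P3 (3.49 ± 0.27, at 2806 bp). They fell near MIR3938 (−2.93 ± 0.22, at 7135 bp), AC013738.1 (−2.99 ± 0.24, at 55517 bp) and MIR1273H (−3.68 ± 0.30, at 12471 bp).

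The intermediate progenitor list rose as a set (camera adjusted p = 0.000328, and adjusted p = 0.898 with an estimated correlation). Of its 16 measured genes 8 rose and none fell, over all regions and adjusted over the list alone, among them the Notch ligand gene DLL3 (log2 2.37 ± 0.26) and NEUROD4 (1.56 ± 0.24). Among 20 measured excitatory neuron genes 10 rose and none fell by either adjustment, with STMN2, a regulator of microtubules (2.00 ± 0.25), and NEUROD6 (1.29 ± 0.22) besides MYT1L and NEUROD2 (camera adjusted p = 0.000895, and adjusted p = 0.898 with an estimated correlation). The axon and synapse list rose (adjusted p = 0.0393, and adjusted p = 0.898 with an estimated correlation), with 6 of 18 genes up, such as SYT4 (1.03 ± 0.25), and NTM down (−1.0 ± 0.24). Its adjusted p was 0.127 without bRG replicate 2, 0.0908 without bIP replicate 4 and 0.161 within the second series. The list's call was lost in 10 of 21 alternatives, also without the series term, with DESeq2 size factors and with no filter. SLIT1 (0.89 ± 0.26), which encodes an axon guidance ligand, had an adjusted p of 0.0701 without bRG replicate 1, 0.078 without bRG replicate 2 and 0.0659 without bIP replicate 5. BCL11B, which encodes a transcription factor of deep-layer neurons, rose by 0.66 ± 0.23 (adjusted p = 0.023). That call was lost without bRG replicate 1 (0.182), bRG replicate 2 (0.0904), bIP replicate 4 (0.149) or bIP replicate 5 (0.0937).

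The basal radial glia list fell in bIP (camera adjusted p = 0.000328, and adjusted p = 0.898 with an estimated correlation). Of its 16 measured genes 7 fell, and 10 when adjusted over the list alone, with SLCO1C1, ACSBG1 (log2 −2.52 ± 0.35), FAM107A (−1.46 ± 0.23) and PDGFD (−0.96 ± 0.21) as examples. HOPX did not pass (20.9 ± 3.32 to 14.6 ± 2.41 CPM, log2 −0.60 ± 0.24, adjusted p = 0.058). Of 7 apical radial glia genes CCN1 (−1.07 ± 0.21) and PROM1 (−0.78 ± 0.19) fell, and the list did not pass (adjusted p = 0.117). Of 15 shared radial glia genes 4 fell, or 3 when adjusted over the list alone (NES, HES1, PAX6 and VIM over all regions), and the list did not pass (adjusted p = 0.112). PAX6 changed by −0.67 ± 0.24 (adjusted p = 0.029), which became 0.136 without bRG replicate 1, 0.128 without bRG replicate 2 and 0.0645 without bIP replicate 5. HES1 (−0.63 ± 0.22, adjusted p = 0.024) became 0.233 and 0.057 without bRG replicates 1 and 2, and VIM (−0.56 ± 0.21, adjusted p = 0.041) 0.216 and 0.127. VIM also missed the threshold without bIP replicate 1 (0.0533) or 2 (0.0574). SOX2 did not pass (49.0 ± 3.71 to 32.9 ± 7.73 CPM, log2 −0.39 ± 0.20, adjusted p = 0.141).

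Some promoters on the lists of cell types outside the sort moved as well, which does not show that such cells were present. The counts below were not set against the share of all promoters that moved. The mesenchyme list fell (camera adjusted p = 0.0134, and adjusted p = 0.898 with an estimated correlation), with 3 of 9 genes down by either adjustment, FOXC2 (log2 −1.31 ± 0.28), FOXC1 (−0.89 ± 0.24) and COL1A1 (−0.73 ± 0.20). The list had an adjusted p of 0.106 within the second series, FOXC1 one of 0.0622 without bRG replicate 1 and COL1A1 one of 0.0566 without bRG replicate 2. In the GABAergic lineage list GAD1 rose (0.72 ± 0.20, but adjusted p = 0.079 without bRG replicate 1) and NPY fell (−1.30 ± 0.23) of 14 genes (adjusted p = 0.631). Among oligodendrocyte and astrocyte genes 3 of 9 fell, or 2 adjusted over the list alone, S100B, AQP4 and CSPG4 over all regions (list adjusted p = 0.0956). Without bRG replicate 1 their adjusted p were 0.0874, 0.137 and 0.223, and CSPG4 had 0.15 without bRG replicate 2 and 0.0736, 0.0707 and 0.0573 without bIP replicates 1, 2 and 3. OTX2 fell in the choroid plexus list (−0.85 ± 0.22, adjusted p = 0.0902 without bRG replicate 1, list adjusted p = 0.235). DPPA4 fell in the pluripotent list (list adjusted p = 0.827, gene adjusted p = 0.171 and 0.0903 without bRG replicates 1 and 2 and 0.0544, 0.0536 and 0.112 without bIP replicates 1, 4 and 5).

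Cell cycle genes CCND1, PLK1 and AURKB fell, 3 of 15 over all regions and 1 adjusted over the list alone (list adjusted p = 0.121). They no longer passed without bRG replicate 1, with adjusted p of 0.0505, 0.204 and 0.340, and without bRG replicate 2 PLK1 had 0.0575 and AURKB 0.0876. Without bIP replicate 5 PLK1 had 0.0664 and AURKB 0.112, and AURKB also missed it without bIP replicate 1 (0.0600), 2 (0.0552) or 3 (0.0531). In the Notch pathway list DLL3 and DLL4 (1.45 ± 0.25) rose and HES1 fell of 7 genes, with a median of −0.09 and an upward test (adjusted p = 0.431). Of 21 morphoregulatory genes DOCK1 (−0.90 ± 0.22), ITGB5 (−0.87 ± 0.22) and LPAR1 (−0.73 ± 0.22) fell, which encode a Rac activator, an integrin subunit and a lysophosphatidic acid receptor. LPAR1 became 0.0997 without bRG replicate 1, and the list had a median of 0.02, a downward test and an adjusted p of 0.554. No housekeeping gene of 8 passed (list adjusted p = 0.743).

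In all, 73398 regions (36.5% of those tested) differed between bIP and bRG, 41053 higher and 32345 lower in bIP, and 35940 and 25722 of these by at least 2-fold. Lower regions outnumbered higher ones with no filter (37246 higher and 37302 lower) and with a minimum of 10 CPM in 2 libraries (12899 and 13089). Within the second series, which holds all bRG libraries, 69470 regions differed, 38569 higher and 30901 lower. Comparisons with bRG rest on 2 libraries, both of the second series. Of the 58 named regions past the threshold in this comparison, 17 lost it without at least 1 of the 7 libraries compared and 9 within the second series. Those 9 were PAX6 (adjusted p = 0.142), HES1 (0.266), VIM (0.251), PLK1 (0.0752), AURKB (0.186), CSPG4 (0.240), COL1A1 (0.074), FOXC1 (0.0639) and LPAR1 (0.0859). Without the series term S100B (0.598), SLIT1 (0.184), PLK1 (0.276) and AURKB (0.0806) missed the threshold. So did AURKB (0.0506), CSPG4 (0.0505) and VIM (0.0568) with DESeq2 size factors, AURKB (0.0557), CSPG4 (0.0556) and HES1 (0.0596) with the 2 groups alone, and BCL11B (0.0706) with no filter. With the closest pairs summed BCL11B (0.112), VIM (0.0523), CSPG4 (0.0525) and GAD1 (0.0502) missed it.

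**Figure D2:**
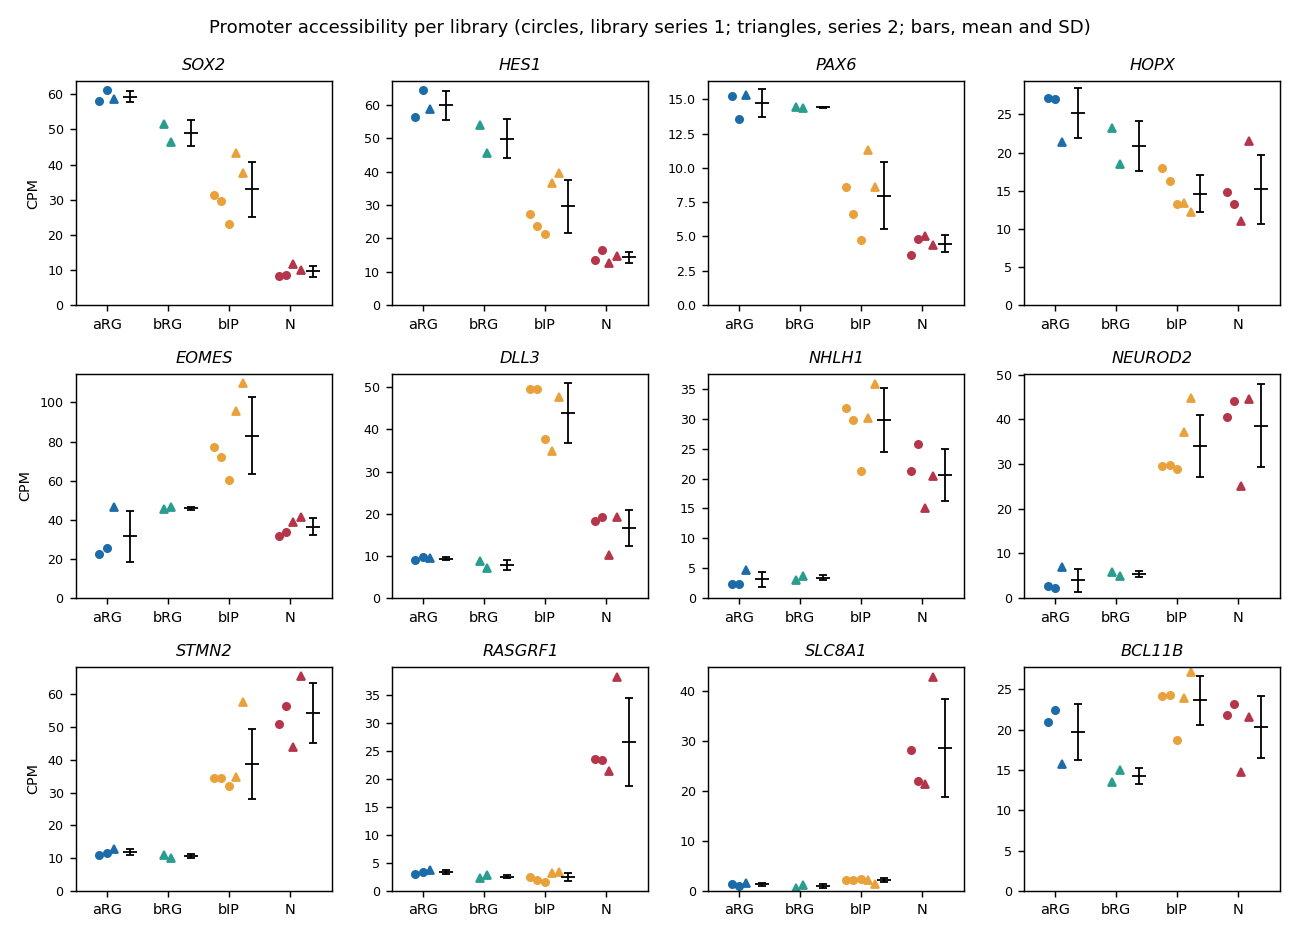
Promoter accessibility in CPM of 12 named genes, with 1 symbol per library (circles for the first library series, triangles for the second) and bars for mean and SD. DLL3 and NHLH1 stand highest in bIP, RASGRF1 and SLC8A1 in N, and SOX2 falls from 32.9 CPM in bIP to 9.60 CPM in N.

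The comparison of N with bIP asks which accessibility changes accompany neuronal differentiation. The promoter of RASGRF1, a calcium-dependent activator of Ras (chromosome 15, 54442248 to 54444133), rose from 2.47 ± 0.755 CPM in bIP (n = 5) to 26.6 ± 7.78 CPM in N (n = 4), a log2 change of 3.38 ± 0.20 (adjusted p = 1.3e-11). SLC8A1, which encodes a sodium/calcium exchanger (chromosome 2A, 56738640 to 56740291), rose from 2.08 ± 0.389 to 28.6 ± 9.89 CPM (log2 3.76 ± 0.23, adjusted p = 1.8e-11). EOMES fell from 83.0 ± 19.8 to 36.5 ± 4.48 CPM (log2 −1.22 ± 0.15, adjusted p = 2.8e-07). SOX2 (chromosome 3, 178123597 to 178125650) fell from 32.9 ± 7.73 to 9.60 ± 1.56 CPM (log2 −1.80 ± 0.16, adjusted p = 1.4e-09). NEUROD2 did not change past the threshold, at 34 ± 6.87 CPM in bIP and 38.6 ± 9.25 CPM in N (log2 0.19 ± 0.21, adjusted p = 0.462), nor did BCL11B (log2 −0.22 ± 0.16, adjusted p = 0.276) or HOPX (0.08 ± 0.19, adjusted p = 0.743).

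The other promoters that rose with the smallest p were those of PTPN5 (log2 3.09 ± 0.22), SLC41A2 (3.03 ± 0.21), PDYN (2.83 ± 0.19), RESP18 (2.72 ± 0.19), TENM2 (2.59 ± 0.18) and HS3ST2 (2.38 ± 0.19). PTPN5 encodes a striatum-enriched tyrosine phosphatase, PDYN the precursor of dynorphin and TENM2 a teneurin that binds latrophilins at synapses. Those that fell were ENTHD1 (−3.49 ± 0.28), DCT (−2.89 ± 0.24), MPP7 (−2.88 ± 0.26), LRRC52 (−2.26 ± 0.18), ZC3H12C (−2.05 ± 0.18), SOX21 (−2.0 ± 0.17) and BTBD17 (−1.93 ± 0.17). SOX21 encodes a transcription factor of neural progenitors. The distal regions with the smallest p rose near AC020551.1 (log2 4.56 ± 0.26, at 23062 bp), MRPL30P1 (4.49 ± 0.25, at 2840 bp) and AC078785.2 (3.33 ± 0.19, at 6256 bp). They fell near PLSCR4 (−3.96 ± 0.21, at 3507 bp), AL008627.1 (−3.59 ± 0.19, at 65657 bp) and FOXP1-AS1 (−3.49 ± 0.19, at 183907 bp).

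The lists of shared radial glia, basal radial glia and intermediate progenitor genes fell from bIP to N, while the apical radial glia list did not pass. Counts of list members, in this and the other comparisons, were not set against the share of all promoters past the threshold. A count alone therefore does not show that a list stands out. Of 15 shared radial glia genes 10 fell, and 11 adjusted over the list alone, such as GLI3 (log2 −1.02 ± 0.16), HES1 (−1.05 ± 0.17) and FABP7 (−0.97 ± 0.16), besides PAX6 (−0.87 ± 0.19). The list passed (camera adjusted p = 0.00167, and adjusted p = 0.898 with an estimated correlation). Of 16 basal radial glia genes 9 fell by either adjustment, with PDGFD (−1.51 ± 0.17), BMP7 (−1.04 ± 0.15), TNC (−0.91 ± 0.16) and FAM107A (−0.82 ± 0.19, but adjusted p = 0.0548 with a minimum of 10 CPM) as examples (camera adjusted p = 0.00994, and adjusted p = 0.898 with an estimated correlation). Of 16 intermediate progenitor genes 10 fell, and 11 adjusted over the list alone, among them DLL3 (−1.39 ± 0.18), NEUROG1 (−1.35 ± 0.16) and NEUROD4 (−1.17 ± 0.17), with the list at an adjusted p of 0.00678, and adjusted p = 0.898 with an estimated correlation. The Notch list fell with 6 of 7 genes by either adjustment, such as HEY2 (−1.22 ± 0.18) and LFNG (−0.73 ± 0.18, but adjusted p = 0.103 within the first series), at an adjusted p of 0.0127, and adjusted p = 0.898 with an estimated correlation. Oligodendrocyte and astrocyte genes also fell, 5 of 9 and 6 adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.898 with an estimated correlation). GFAP (−1.63 ± 0.23), SOX10 (−1.44 ± 0.24), S100B (−1.28 ± 0.24) and CSPG4 (−1.13 ± 0.17) were among them. Within the second series alone the adjusted p was 0.171 for basal radial glia, 0.0582 for intermediate progenitors and for oligodendrocytes and astrocytes, and 0.0531 for Notch.

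The excitatory neuron list did not pass as a set (camera adjusted p = 0.725). Of 20 genes, 3 rose, STMN2, MAPT and CAMK2B (log2 1.82 ± 0.18), and 7 fell, by either adjustment. Those that fell included FEZF2 (−0.58 ± 0.15), CUX2 (−0.80 ± 0.20), SOX5 (−0.53 ± 0.14), CUX1, GAP43 and TBR1, of which FEZF2, CUX2, SOX5 and TBR1 encode transcription factors known for layer identity. CUX2 had a log2 change of −0.22 within the first series (adjusted p = 0.278). SOX5 had one of −0.58 within the second (0.0705), −0.16 with loess offsets (0.267) and −0.23 with a minimum of 10 CPM (0.0816). Of 18 axon and synapse genes SYT4 (1.15 ± 0.18), GRIN2B (0.87 ± 0.17), CNTN1 and STMN2 rose and 6 fell, among them ROBO2 (−0.71 ± 0.15) and NCAM1 (−0.61 ± 0.15, but adjusted p = 0.0548 within the first series), with a median of −0.06 and an upward test (adjusted p = 0.638). In the GABAergic list SST (1.03 ± 0.19) and LHX6 rose and 9 of 14 fell, such as LHX8 (−1.71 ± 0.18) and DLX1 (−1.14 ± 0.18), at an adjusted p of 0.133. Of 21 morphoregulatory genes 7 fell, or 6 adjusted over the list alone (list adjusted p = 0.121), with ITGB8 (−0.78 ± 0.16), CDH2 (−0.53 ± 0.17), ROCK2 (−0.49 ± 0.15) and MYO10 (−0.48 ± 0.16) among them. Within the first series CDH2 (adjusted p = 0.364), ROCK2 (0.172) and MYO10 (0.259) missed the threshold, as they did with the 2 groups alone (0.0597, 0.0517 and 0.0634), and MYO10 had 0.0652 with loess offsets.

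Of the remaining lists, 4 of 7 apical radial glia genes fell, and 5 adjusted over the list alone, such as FBXO32 (log2 −0.65 ± 0.19), PROM1 (−0.55 ± 0.15) and PARD3 (−0.50 ± 0.15) (list adjusted p = 0.217). Within the first series FBXO32 (log2 −0.18, adjusted p = 0.406) and PARD3 (−0.28, 0.180) missed the threshold. With loess offsets PROM1 (−0.17, 0.105) and PARD3 (−0.15, 0.0717) missed it. Of 15 cell cycle genes 3 fell by either adjustment, CCND1 (−1.16 ± 0.17), CCNE2 (−0.79 ± 0.16) and AURKB (−0.51 ± 0.18, but adjusted p = 0.0541 without bIP replicate 4, 0.0593 and 0.0662 within the first and second series, 0.455 with loess offsets and 0.160 with a minimum of 10 CPM), at a list adjusted p of 0.163. Mesenchyme genes fell at PDGFRB (−1.19 ± 0.19), FOXC1 (−1.19 ± 0.20), TBX18 (−0.83 ± 0.17) and TWIST1 (−0.63 ± 0.17, but adjusted p = 0.0833 within the first series and 0.123 with loess offsets) and rose at LUM, of 9 (list adjusted p = 0.194). In the choroid plexus list FOLR1 (−1.68 ± 0.30), AQP1 (−1.19 ± 0.20), OTX2 (−1.13 ± 0.19) and MSX1 fell and RSPO2 (0.85 ± 0.16, but adjusted p = 0.0694 within the second series) and LMX1A rose, of 8 (list adjusted p = 0.638). DPPA4 fell (−0.84 ± 0.30, adjusted p = 0.020, and 0.0724 without N replicate 1, 0.0523 without N replicate 4, 0.0548 and 0.175 within the first and second series, 0.0787 with total counts and 0.0799 without the series term), and the pluripotent list had an adjusted p of 0.548. SDHA (−0.46 ± 0.15) was the only housekeeping gene of 8 to pass (list adjusted p = 0.429), and it missed the threshold with loess offsets (0.089), the 2 groups alone (0.0655) and within the first series (0.236).

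Between N and bIP 110850 regions (55.2%) differed, 57834 higher and 53016 lower in N, and 43728 and 31181 of these by at least 2-fold. The first series alone gave 51924 regions higher and 50185 lower, and the second 50830 and 41986. Lower regions outnumbered higher ones with loess offsets (59191 higher and 61099 lower) and without N replicate 3 (56802 and 58887). The size of the difference depended on the series at 16743 regions (interaction, adjusted p under 0.05). Of the 72 named regions past the threshold, 12 lost it within the first series and 4 within the second.

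**Figure D3:**
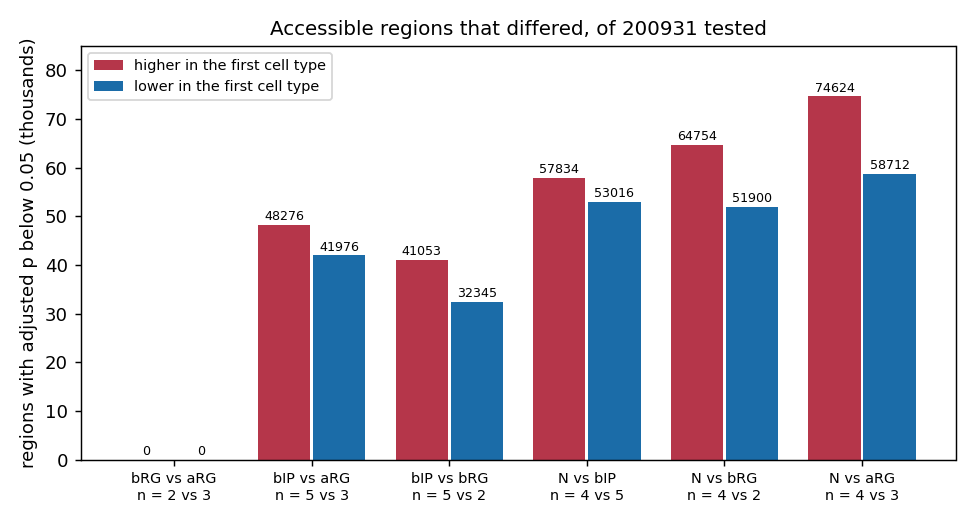
Numbers of regions past the threshold per comparison (vertical axis, in units of 1000 regions), with higher (red) and lower (blue) values in the first-named cell type, with the numbers of libraries under each pair. The count runs from 0 for bRG against aRG to 133336 for N against aRG.

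The remaining comparisons set N and bIP against aRG and N against bRG. Between bIP and aRG 48276 regions were higher and 41976 lower in bIP, between N and bRG 64754 were higher and 51900 lower in N, and between N and aRG 74624 were higher and 58712 lower in N. Which direction held more regions depended on the setting. For bIP against aRG it was 45453 higher and 50714 lower with loess offsets, 42440 and 50783 with no filter, 36537 and 42785 without aRG replicate 2, and 40815 and 47793 without bIP replicate 4. Without N replicate 3 it was 60769 and 60925 for N against bRG and 67892 and 68931 for N against aRG, and without aRG replicate 2 it was 62036 and 62236 for N against aRG. Within the first series, bIP against aRG gave 51279 higher and 44934 lower and N against aRG 72368 and 57968. Within the second series the counts were 27670 and 21811 for bIP against aRG, 61222 and 46801 for N against bRG, and 53898 and 39633 for N against aRG. In that series aRG has 1 library, replicate 3, which is assumed to vary like the libraries of the other groups. The effect depended on the series at 19 regions for bIP against aRG and at 5568 for N against aRG.

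Member counts in these comparisons were likewise not set against the share of all promoters past the threshold. From aRG to bIP, 9 of 15 shared radial glia genes (camera adjusted p = 0.00759) and 12 of 16 basal radial glia genes (adjusted p = 0.000601) fell, HOPX among the latter (log2 −0.78 ± 0.19). Intermediate progenitor genes rose, 8 of 16 and 9 adjusted over the list alone (adjusted p = 0.000300), EOMES by 1.40 ± 0.17. Excitatory neuron genes rose at 8 of 20 and fell at FEZF2 and SOX5 (adjusted p = 0.00131). Cell cycle genes fell at 6 of 15 (adjusted p = 0.0270, and 0.0505 without aRG replicate 2), and mesenchyme genes at 6 of 9 (adjusted p = 0.0177). From aRG to N, 12 of 15 shared radial glia genes (adjusted p = 0.000607), 15 of 16 basal radial glia genes (0.000328), 12 of 15 cell cycle genes (0.0177), 8 of 9 mesenchyme genes and 7 of 9 oligodendrocyte and astrocyte genes (0.0153 each) fell. Of 21 morphoregulatory genes 13 fell, GPSM2, ITGAV and MARCKS among them (median log2 −0.56, adjusted p = 0.0393, and 0.0624 without aRG replicate 2). The morphoregulatory call was also lost within the first series, with the 2 groups alone, with loess offsets and with DESeq2 size factors. So it was with a promoter window of 500 bp and with the closest pairs summed. Of 8 housekeeping genes B2M, PPIA, SDHA and YWHAZ also fell with TMM scaling, or 2 adjusted over the list alone (median −0.43, list adjusted p = 0.295), but with loess offsets PPIA stood at 0.10 (adjusted p = 0.143), SDHA at −0.10 (0.201) and YWHAZ rose by 0.13 (0.0151). PPIA and YWHAZ missed the threshold without aRG replicate 1 (0.0642 and 0.0874), aRG replicate 3 (0.0858 and 0.0745) or N replicate 1 (0.0823 and 0.105). The median over all promoters was −0.26. The cell cycle list had a median of −0.70. Excitatory neuron genes rose at 9 and fell at 6 of 20 (adjusted p = 0.0281). From bRG to N, shared radial glia (9 of 15, adjusted p = 0.00178), basal radial glia (12 of 16, 0.000300), mesenchyme (7 of 9, and 8 adjusted over the list alone, 0.00994), oligodendrocyte and astrocyte (6 of 9, 0.00958) and cell cycle genes (6 of 15, 0.0470) fell. The cell cycle call was lost in 13 of 20 alternatives, among them those without bRG replicate 1 (0.0951), bRG replicate 2 (0.0555) or N replicate 3 (0.0884). Excitatory neuron genes rose at 10 and fell at 5 of 20 (adjusted p = 0.0270). From bRG to N the mesenchyme and excitatory neuron calls were lost within the second series and with the 2 groups alone. With all regions within 50 kb, the mesenchyme and cell cycle calls of these comparisons were lost. The excitatory neuron calls of N against aRG and bRG were lost there too. Within the second series, where aRG has 1 library, the shared radial glia, mesenchyme and cell cycle calls of bIP against aRG were lost. So were the mesenchyme, excitatory neuron, cell cycle and morphoregulatory calls of N against aRG. With a minimum of 10 CPM the oligodendrocyte and astrocyte list had a camera adjusted p of 0.223 for N against aRG and 0.156 for N against bRG. Each list that passed in these comparisons had an adjusted p of 0.898 with an estimated correlation. Median and test differed in sign, without passing, for intermediate progenitor genes from bRG to N (median −0.04, adjusted p = 0.541) and from aRG to N (−0.12, 0.486), and for Notch genes from aRG to bIP (−0.36, 0.677).

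**Figure D4:**
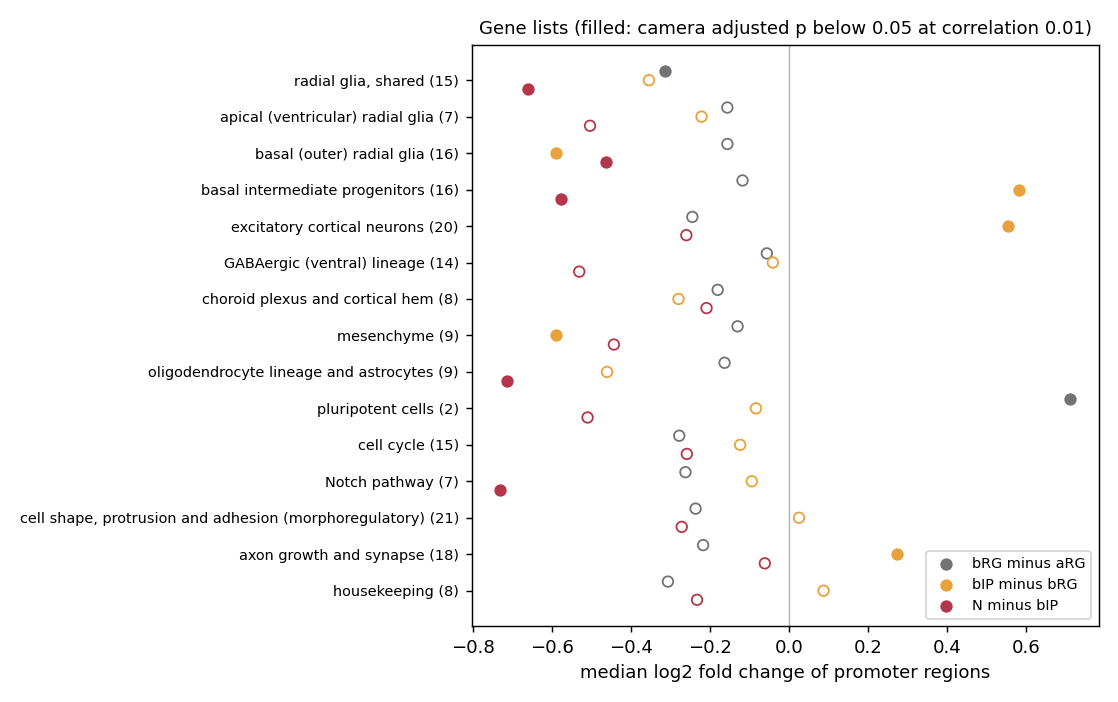
Median log2 fold change of the promoter regions of each gene list, with the number of measured genes in parentheses, for the 3 main comparisons; filled symbols passed camera at a preset correlation of 0.01. No list passed with an estimated correlation, where the smallest adjusted p was 0.898.

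With TMM scaling, changes were less frequent at promoters than elsewhere. Promoters of protein-coding genes made up 1.86% of the regions that differed between bIP and bRG and 7.23% of the others (Fisher's exact test, two-sided, odds ratio 0.243, 95% interval 0.229 to 0.258). For N against bIP the shares were 2.68% and 8.44% (odds ratio 0.299, interval 0.286 to 0.313). With loess offsets the share for N against bIP was 5.56% and the direction turned. The odds ratios were 0.329 for bIP against aRG, 0.271 for N against bRG and 0.405 for N against aRG. The regions of a genome are not independent, so the exact p-values, all at the floor of 1e-300 used here, are not interpreted.

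Regions that change later were also examined between the radial glia. The 57834 regions higher in N than in bIP had a median log2 difference of −0.06 between bRG and aRG (camera adjusted p = 0.460), and the 53016 higher in bIP had 0.01 (adjusted p = 0.490). With an estimated correlation the adjusted p was 0.811 for both.

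The deposited peak sets, 1 per cell type, without replicates and with no genome build stated, held 73255 regions in aRG, 72155 in bRG, 71389 in bIP and 73136 in N, covering 64.5 to 69.5 Mb. Of bRG regions 83.4% (Wilson 95% interval 83.1 to 83.7) were covered over at least 50% of their length by aRG regions. The share of bIP regions covered was 64.7% by bRG (interval 64.3 to 65.0) and 60.9% by aRG. The share of N regions covered was 64.4% by bIP (interval 64.1 to 64.8), 50.0% by bRG and 49.1% by aRG. Regions that no other set touched made up 7.77% of the bRG set, 11.8% of the aRG set, 14% of the bIP set and 29.0% of the N set. None of the sets has a region on chromosomes 2A or 2B, where the count table has 17364.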

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

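All tests of explanations in this part were chosen after the results were seen. A library was singled out when its gap to the nearest other library of its group exceeded Dixon's 95% limit, which chance alone exceeds in about 1 in 20 groups, and 12 of 236 values did. In N, replicate 4 stood high at RASGRF1 (38.1 CPM, the others 21.4 to 23.5), FEZF2 (44.6 CPM, the others 29.9 to 32.4) and the region near AC078785.2 (31.3 CPM, the others 18.2 to 19.9). N replicate 3 stood low at DLL3 (10.2 CPM, the others 18.2 to 19.1) and AURKB (6.58 CPM, the others 8.26 to 8.49). N replicate 1 stood low at PROM1 (15.3 CPM, the others 17.5 to 17.9) and FOXC2 (1.13 CPM, the others 1.49 to 1.55), and N replicate 2 stood high at CSPG4 (6.11 CPM, the others 4.37 to 4.56). In bIP, replicate 5 stood high at STMN2 (57.5 CPM, the others 32.0 to 34.6) and CUX2 (40.7 CPM, the others 26.2 to 30.1) and low at SLC8A1 (1.40 CPM, the others 2.17 to 2.36).

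The 3 regions with the most counts, on chromosome 3 (78734681 to 78737112 and 78740748 to 78742692) and chromosome 9 (74881480 to 74883297), held 0.907% of the counts of bIP replicate 3 and 0.218% to 0.339% in the other bIP libraries. Over all libraries the share ran down to 0.0356% in bRG replicate 1.

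At 16743 regions the difference between N and bIP was not the same in the 2 library series by a test of the interaction. The series themselves differed at 31827 regions with the series term, 18794 higher and 13033 lower in the second, and within single cell types at 28010 regions in bIP and 31038 in N. In aRG it was 6890 regions, where the second series has 1 library and the other groups supply its spread.

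Regrouping the libraries tested whether the counts of regions could arise by chance, on 20000 regions drawn with a fixed seed. For bIP and aRG, 1 of 56 splits of the 8 libraries, the real one, gave as many regions as its 8924, and the highest other gave 0. For N and bIP, 1 of 100 splits drawn gave as many as the real 11026, and the highest other, which set bIP replicates 1, 3, 4 and 5 against the rest, gave 7398. For N and aRG, 1 of 35 splits gave as many as the real 13229, and the highest other, which moved only N replicate 3 to the side of aRG, gave 10123. Among splits that keep each group's number of libraries in each series, 1 of 30 gave as many for bIP and aRG (highest other 0) and 1 of the 45 drawn for N and bIP (highest other 7398). If every library is a separate sample, these shares (0.0333 and 0.0222) argue against chance assignment of the libraries to groups for these 2 counts. Each is the smallest share that these splits can give, and neither was adjusted for the number of comparisons tested, so chance is not excluded. For N and aRG the share is under 0.05 over all 35 splits only (0.0286), because the 18 splits that keep the series are too few for such a share. If aRG replicates 1 and 2, and bIP replicates 1 and 2, are each 1 culture, both comparisons with aRG have too few splits for a share under 0.05. The test then cannot argue against chance for them. The comparisons with bRG have 2 libraries on a side and were not tested in this way.

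A promoter closed in one series and open in the other was that of PEG3, an imprinted gene that encodes a zinc finger protein (chromosome 19, 46654113 to 46655504). It held 0.365 ± 0.215 CPM in the first series and 88.6 ± 21 CPM in the second (SD, n = 7 each, log2 8.07 ± 0.24, adjusted p = 2.2e-17). A mix of sorted cell types that differs between the series is argued against, since the difference within aRG, bIP and N was 8.29, 8.72 and 7.27. Depth is argued against by PEG3 counts of 3 to 12 per library in the first series and 1227 to 2370 in the second. Library totals ran from 12834983 to 26660427 in the first series and from 16918366 to 24561258 in the second. The 3538 promoters of like abundance differed by a median of 0.032, but scaling brings this median near 0, so it does not test depth. The imprinted promoters other than PEG3 did not differ more than random promoter lists did (percentile 37.8 of 10000 lists, 36 promoters measured, 3 higher and 1 lower in the second series). A candidate explanation that stays open is a different epigenetic state of this promoter in the cultures behind each series; the design names no group on which to test it.

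A domain on chromosome 10 around TCERG1L (126552749 to 127224520, 51 neighbouring regions) lay lower in the second series, with a median log2 difference of −3.04. In 200 shuffled orders of the regions, runs held at most 4. Shuffling treats neighbouring regions as independent, and runs of regions higher in the second series reached 23. The comparison with shuffled orders therefore does not single out this domain. Loss of both copies in all cells is argued against by counts of 9 to 40 at the TCERG1L promoter in the second series, against 58 to 370 in the first. Loss of 1 of 2 copies in all cells is argued against by a median of −2.70 ± 1.30 (SD) over the 31 regions listed with TCERG1L, of which 29 were lower. Whether other genes known for incomplete methylation in pluripotent lines also lay lower stays open. The test covered only PTPRT, the 1 listed gene that was measured, at a log2 difference of 0.99, and 1 gene cannot decide it. It did not cover 2 lower domains on chromosome 12. Regions listed with TMEM132C lay in one (53 regions, median −3.16) and regions listed with TMEM132D-AS1 in the other (15 regions, −2.25). The tests of copy loss covered TCERG1L only, not a further lower domain on chromosome 10 (125550655 to 126300018, 38 regions, median −3.14). Loss in part of the cells and a closed chromatin state may each underlie the TCERG1L domain and were not separated. The design names no group on which to test a biological explanation.

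The 13029 regions past the threshold and at least 4-fold higher in N than in bIP within the first series took 1.16% of the counts of aRG replicate 3, 0.929% and 1.02% of those of the bRG libraries, and 0.880% and 0.789% of those of aRG replicates 1 and 2. A series effect alone predicts no gap between aRG replicate 3 and bRG, which share a series. The gap of 0.141 percentage points exceeds the range between libraries of aRG in the first series (0.0905), bRG (0.0897) and bIP in the second (0.0697). It does not exceed that of bIP in the first (0.279), so a series effect is left open. That last range rests on bIP replicate 3, at 1.57% against 1.29% and 1.33% in bIP replicates 1 and 2. Cells of other sorted types among those of aRG replicate 3 remain a candidate source, as the excess over bRG grew with the level in N at like slopes at promoter and other regions (5.05% and 3.86%, a ratio of 1.31). A real difference between aRG and bRG stays open and was not tested apart from these.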

How the results depend on the processing

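Fits within the first series, fits with 1 mean per group and series, the 2-group fit without the series term and the sums of near-identical libraries were added after the data were seen. Of 124 counts of regions under an alternative, 112 lay within 1.5 times the reported count. A result past the threshold in neither fit is counted as unchanged. Between bRG and aRG, DESeq2 gave 7 regions, effects within the second series 1, the 2 groups alone 1125, or 0 without the series term (21268 at an unadjusted p under 0.05 with edgeR), and leaving out 1 library 0 to 11, with 11 without aRG replicate 3; the cause was not tested. A minimum of 10 CPM in 2 libraries gave 30863 (bIP and aRG), 25988 (bIP and bRG), 29999 (N and bIP), 32008 (N and bRG) and 33911 (N and aRG), with fewer regions tested. The second series alone gave 49481 for bIP and aRG, with fewer libraries. Leaving out each library gave 76040 to 88608 (bIP and aRG), 49865 to 73148 (bIP and bRG), 100980 to 115689 (N and bIP), 94926 to 121694 (N and bRG) and 121795 to 136823 (N and aRG).

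With the replicate number as a block, 44832 regions differed between N and bRG and 5899 between bIP and bRG, 5303 of the latter higher and 596 lower in bIP. PAX6, S100B and AURKB turned to 0.19, 0.10 and 0.0103 on the log2 scale between bIP and bRG (adjusted p = 0.916, 0.965 and 0.996). Of the 58 named regions past the threshold there, 37 lost it with the block. The numbers mix the series, and correlations of same-numbered libraries ran from −0.232 to 0.272. With 3 or more pairs not every library correlated best with its own number, so the numbers were not taken to pair the samples. These correlations were not corrected for the series, and no other pairing was tried. Another pairing of the cell types therefore stays possible. For gene lists 1772 results kept their side of the threshold without a call turning, of which 568 were past it in both fits and 1204 in neither, 75 of the latter in the other direction. Of the rest 107 calls were lost, 56 were gained and 3 turned direction. These were the choroid plexus list between bRG and aRG (adjusted p = 0.0249, lower) and the pluripotent list between N and aRG (0.0233, lower) with all regions within 50 kb, and the apical list between bRG and aRG with loess offsets (0.0164, higher). Of the named regions 2721 results kept their side of the threshold (2524 past it in both fits and 197 in neither, 16 of these in the other direction), 142 calls were lost, 15 were gained and 3 turned, those named for the block.

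The promoter share of changed regions kept its direction in 104 results and turned with loess offsets for N and bIP (5.56%); the cause was not tested. It ran from 1.17% to 10.5% for bIP and bRG and from 2.21% to 15.1% for N and bIP, highest with the minimum of 10 CPM. Lower regions outnumbered higher ones in 8 of 21 alternatives for bIP and aRG (45.5% to 57.4% higher), 2 of 19 for bIP and bRG, 4 of 22 for N and bIP, 1 of 18 for N and bRG and 4 of 20 for N and aRG. Loess offsets moved the median log2 difference of all regions by −0.36 for N and aRG, −0.25 for N and bRG, −0.22 for N and bIP and −0.11 for bIP and aRG. Promoters whose fall was lost with loess offsets moved the other way. For N against bIP PROM1 went from −0.55 to −0.17 and SOX5 from −0.53 to −0.16. For N against aRG PPIA went from −0.46 to 0.10. The size of such falls thus depends on the scaling, and loess values of most named promoters are not given here. Total counts moved it by 0.18 for bRG and aRG, 0.17 for N and aRG, −0.11 for bIP and bRG and 0.10 for N and bIP, and DESeq2 size factors by −0.12 for N and aRG. Beyond scaling choices, it moved by up to 0.29 with the minimum of 10 CPM (N and bIP), −0.19 with no filter, −0.20 with near-identical libraries summed, −0.19 without aRG replicate 2 and −0.18 with the 2 groups alone (N and aRG each). An overlap of at least 1 bp gave shares of 84.4% (bRG by aRG), 63.2% (bIP by aRG), 67.4% (bIP by bRG), 65.8% (N by bIP), 52.6% (N by bRG) and 51.3% (N by aRG). The stricter part of each set by q gave 89.8%, 67.2%, 68.2%, 63.3%, 50.8% and 50.7% in that order. Motif tests and a GC correction were not run, since no genome was used here.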

Other observations

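The tests in this part were chosen after the results were seen. With TMM scaling, 49 promoter regions, that of PEG3 included, were at least 4-fold higher in the second library series and 15 at least 4-fold lower. Those higher included CHL1 (log2 5.19), a neural cell adhesion gene, KHDRBS2 (4.30), OCIAD2 (4.17), ZNF441 (3.62), CNTN4 (3.16), which encodes a contactin, and GRM7 (2.87), which encodes a glutamate receptor. Those lower included QPCT, which fell by 3.27, and TCERG1L, which fell by 2.90. Of 31 measured promoters of the clustered protocadherins, cell surface proteins whose promoters are known to be chosen cell by cell, 15 were higher and 6 lower in the second series, 67.7% against 11.6% of all promoters. Of 376 zinc finger promoters 23 were higher and 4 lower, or 7.18%. The mean absolute log2 difference of the zinc finger promoters (0.225) lay at percentile 99.9 of 10000 random lists matched on mean count, whose median was 0.187. The list kept ZNF441, named above, and its share past the threshold lay below the 11.6% of all promoters. The percentile therefore does not show that zinc finger promoters differ as a class. By number of neighbouring regions, the domains lower in the second series with the most were on chromosome 12 (121616856 to 124262308, 53 regions, median −3.16), chromosome 10 around TCERG1L (51 regions, −3.04), chromosome 2B (11052101 to 12911945, 51 regions, −2.58) and chromosome 1 (911109 to 1649855, 47 regions, −2.90). The chromosome 12 domain holds regions listed with TMEM132C. The longest run of regions higher in the second series held 23.

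The count table holds 137 regions on chromosome X, while the peak sets hold 2422 (aRG), 2274 (bRG), 1961 (bIP) and 2153 (N) there. Of the 186885 table regions off chromosomes 2A and 2B, 63.4% were touched by a peak of the 4 sets, and 11.6% after a shift of 50 kb. The peak sets state no genome build, so both counts assume that they are in gorGor6.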
